A study of Mus musculus with 18 samples.

How the data were processed

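RNA sequencing was measured in 18 mouse libraries: BMDM with WT or T166A PPARg (n = 3 each) and cells bound by anti-F4/80 beads from skin wounds at day 6 after injury (n = 6 each). Groups, replicate numbers and the BMDM batches (B1 and B2) were taken from the labels. The deposited values are raw counts per RefSeq transcript, in a table for each cell source. Per the submitters' processing notes, reads were handled with FastQC 0.12.1, cutadapt 4.4, HISAT2 2.2.1 and featureCounts (version not given) on the mm10 build. The strand setting and the handling of reads that overlap several features or map to several places are not given in the sources used here. The values were whole numbers with a different total per library, and reads in exons shared by isoforms had been counted once for each isoform.

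Counts were listed for 45895 transcripts in BMDM and 45843 in skin. Of these, 45744 and 45692 were matched to a gene through the RefSeq annotation and 34 in each table through GENCODE, and 117 in each were not matched and were left out (0.514% and 0.187% of all counts). Each gene was represented by its transcript with the highest summed CPM, so that shared exons were counted once, which gave 26165 and 26149 genes. Several transcripts were listed for 8835 and 8821 of them. Summing over transcripts raised the total 2.05-fold and was run as an alternative. H2-Q7 and H2-Q9 held identical counts. Depth ranged from 40063545 to 44146308 gene counts in BMDM and from 29356302 to 38772922 in skin, and the 50 most abundant genes took 27.2 to 30.3% and 15 to 16.9% of them. No pair of libraries was a duplicate.

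Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr with a minimum count of 10 and a minimum total count of 15, robust quasi-likelihood F test) and Benjamini-Hochberg adjustment, with a threshold of 0.05 and no fold threshold. Each cell source was fitted alone, BMDM with batch and genotype and skin with genotype. Standard errors were computed from the log2 fold change and the F statistic. The biological coefficient of variation was 0.279 in BMDM and 0.133 in skin, with 3 and 10 residual degrees of freedom. The interaction was tested in an edgeR fit over all 18 libraries, and the effects of both sources were compared by the overlap of calls (Fisher's exact test) and by correlation across genes. Whether replicate numbers paired the libraries was checked from the correlation of same-numbered WT and T166A libraries after removing group means. It was 0.199, 0.114 and 0.186 in BMDM, where the batch is given, and -0.045 to 0.089 in skin, where the numbers were not used as pairs.

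Gene lists, the rule for naming genes, tests and most alternatives were chosen before the data were examined. The lists covered 20 pathways (fatty acid synthesis, glycerolipid and phospholipid synthesis, cholesterol synthesis, PPAR targets, LXR targets, fatty acid oxidation, oxidative phosphorylation, glycolysis, alternative activation, pro-inflammatory activation, type I interferon response, MHC class II, growth factors and matrix remodelling, efferocytosis, lysosome, NRF2, endoplasmic reticulum stress, cell cycle, immediate early and heat shock genes, and kinase and nuclear receptor partners of PPARg) and, as a second family, markers of cell types. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), beside camera with an estimated correlation and fry. The rule named Pparg, the 8 largest rises and the 8 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and every T166A library beyond every WT library (predicted genes left out), the 2 members of each pathway list with the smallest adjusted p, the most abundant member of each cell type list, and the 5 interaction genes with the smallest adjusted p in each direction with at least 5 CPM in both sources. List scores were mean log2 CPM with a prior count of 2.

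Alternatives were RLE size factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, a replicate block, no batch term, batch B1 alone, keratinocyte and fibroblast or neutrophil scores as covariates, and leaving out each library. Chosen after seeing the data were the sum over transcripts, the adipocyte score as a covariate, removal of each library's transcript length trend (alone or with a replicate block) and a different p for the difference of the separate edgeR fits (with or without the length trend of each source). This p came from a t distribution with Satterthwaite degrees of freedom, on edgeR's moderated standard errors and residual degrees of freedom, adjusted over all genes. Relations between list scores were tested within each genotype by exact permutation. Also chosen after seeing the data was a comparison that no scaling factor changes. For each skin library, log2 CPM (prior count of 2) was centred per gene, and the median over all genes was subtracted from the median over a list, with an exact test over all 924 groupings of 6 libraries. The fits were tested on simulated data with known changes. In BMDM, 9.2%, 49.2% and 85.7% of 1.5-fold, 2-fold and 4-fold changes were recovered, with 5 false calls among 96; in skin these were 59.7%, 92.4% and 98.5%, with 11 among 192. Of 20 unchanged lists, 0 were called in either source by camera, but the simulated genes varied independently of each other, unlike genes of real libraries. When the real libraries were split in other ways, camera called a median of 7 of the 20 pathway lists in each source. In all of these BMDM splits and many of the skin splits, the genotypes were unequal on each side. Part of a genotype difference therefore remained, and this median is no pure background. The interaction fit made 275 false calls among 365 when each source had its own spread, and DESeq2 534 among 634. The simulated data were analysed after the first fit of the real data.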

Results

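Counts from RNA sequencing were analysed for 18 mouse macrophage libraries with either the wild-type (WT) form of PPARg or the T166A form, in which alanine replaces a phosphorylatable threonine of this lipid-sensing nuclear receptor. Bone marrow-derived macrophages (BMDM), which are grown from marrow cells with the growth factor M-CSF (50 ng/ml, 7 days), gave 3 libraries per genotype. In each genotype, BMDM replicates 1 and 2 belonged to batch B1 and replicate 3 to batch B2. Cells captured with beads against F4/80, a macrophage surface protein, from dorsal skin wounds at day 6 after injury gave 6 libraries per genotype, without a batch label. The BMDM libraries held 40063545 to 44146308 gene counts and the skin libraries 29356302 to 38772922. The labels do not clearly say that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples. The extraction protocol speaks of adipocytes differentiated in vitro, whereas the labels of all libraries name macrophages. Levels are given as CPM (a gene's share of the library's counts, scaled to 1e6), mean ± SD (n = 3 per genotype in BMDM, n = 6 in skin), and log2 fold changes are T166A over WT with their standard error (SE). The macrophage gene Lyz2 was at 30140 ± 6680 CPM in WT BMDM, where 2 of 12 adipocyte markers were measured, and at 5420 ± 480 CPM in WT skin libraries, against 0.916 ± 0.375 CPM of the adipocyte gene Adipoq. The libraries are therefore described as macrophages, which does not exclude RNA of other cells in the skin fraction. Gene positions refer to GRCm38 (mm10).

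The first comparison asked how the T166A form changes the transcriptome of cultured BMDM. Interferon-induced genes were higher in T166A BMDM by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.25) or by fry (0.0968), and 3 of 31 listed members passed over all genes tested by edgeR. Ifit2 (chromosome 19, 34550550 to 34576534), which encodes an interferon-induced RNA-binding protein, rose 2.56-fold from 50 ± 3.08 to 129 ± 21.4 CPM. Its relatives Ifit1 and Ifit3 rose 2.12-fold and 1.98-fold. Plau (chromosome 14, 20836662 to 20843388), which encodes the secreted protease urokinase, was the single gene that fell, from 226 ± 33.6 to 104.5 ± 22.5 CPM. Pparg transcripts (chromosome 6, 115360879 to 115490404) did not differ, at 58.5 ± 3.54 CPM in WT and 57.7 ± 3.1 CPM in T166A libraries (log2 fold change -0.02, SE 0.12, edgeR adjusted p = 0.967). A count of Pparg transcripts cannot show a point mutation, so this value does not check the genotype labels.

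Of 13137 genes tested in BMDM, 8 were higher and 1 was lower in T166A by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p of 0.05 the number was 1686, against 657 that chance would give for genes without shared trends. It was 1223 with each library's transcript length trend removed, an alternative chosen after seeing the data, and 929 without a batch term. The excess is therefore not read as an effect of T166A alone. Ifit2 had a log2 fold change of 1.36 (SE 0.15, edgeR adjusted p = 0.0336). The nonclassical MHC class I gene H2-Q7 (chromosome 17, 35439140 to 35443773) rose 2.61-fold, from 34.9 ± 8.36 to 90.3 ± 15.9 CPM (edgeR adjusted p = 0.0336). H2-Q9 held the same counts as H2-Q7 in every library, so the 9 calls stand for 8 distinct measurements. Ifi203, a member of the interferon-inducible p200 family, rose 2.4-fold (edgeR adjusted p = 0.0436), and the membrane protein gene Ms4a4c rose 2.28-fold, from 47.8 ± 16.1 to 109.5 ± 39.4 CPM (edgeR adjusted p = 0.0336). Sptbn1, which encodes a spectrin of the membrane skeleton, rose 2.09-fold, from 30.8 ± 4.43 to 64.3 ± 5.82 CPM. Plau had a log2 fold change of -1.12 (SE 0.14, edgeR adjusted p = 0.0386). The Ifit, Ifi200, Ms4a4 and H2-Q families contain near-identical copies, and how the deposited counts shared such reads is not given in the sources used here. The values per batch come from the libraries by which the genes were selected. The Ifit2 log2 fold change was 1.53 in B1 and 1.01 in B2, that of H2-Q7 1.46 and 1.22, that of Ms4a4c 1.17 and 1.23, that of Sptbn1 1.02 and 1.16, and that of Plau -1.08 and -1.21. Over all 13137 genes, the log2 fold changes of the batches had a Spearman correlation of 0.05 across genes, which are not independent replicates.

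The number of BMDM calls changed when single libraries were left out. Without WT replicate 1, WT replicate 3, T166A replicate 1 or T166A replicate 2, edgeR called 0 genes in either direction, with 1279, 2303, 1071 and 859 genes at an unadjusted p under 0.05. Without WT replicate 2 it called 6 higher and 8 lower, and without T166A replicate 3 it called 18 higher and 0 lower. Leaving out either replicate 3 lets the batch term take up the remaining B2 library, so both fits estimate genotype from the same B1 libraries. Sptbn1 had a log2 fold change of 1.02 in each of them and in B1 alone. Their different counts, 0 and 18 higher, therefore do not show dependence on a single library. Without a batch term the count was 0 (929 genes at an unadjusted p under 0.05), and with transcripts summed per gene, an alternative chosen after seeing the data, it was also 0 (1557 genes). DESeq2 called 231 higher and 138 lower and limma-voom 147 higher and 28 lower in the full set. With the replicate number as a block, Ifi203 had a log2 fold change of 1.27 (SE 0.16), against 1.26 (SE 0.16) without it, and with fewer residual degrees of freedom missed the threshold (edgeR adjusted p = 0.0701, range over its alternatives 1.58e-09 to 0.477). In that fit 8 genes were higher and 2 lower.

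**Figure D1:**
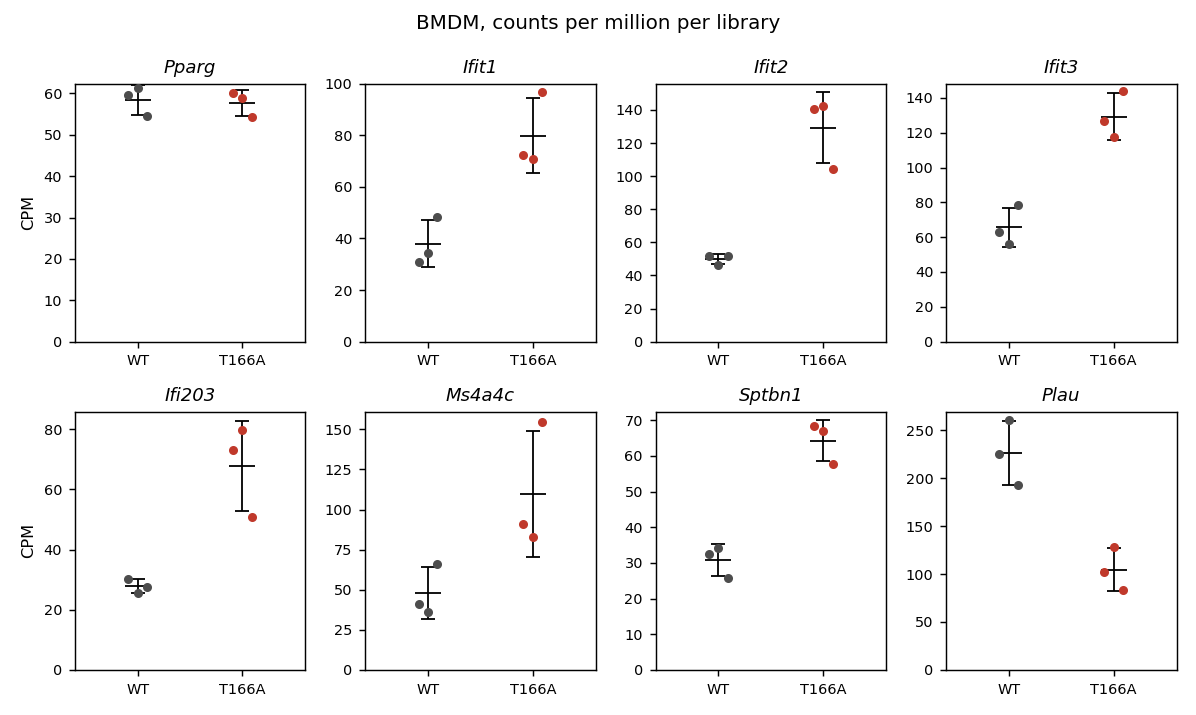
CPM of 8 named genes in the 6 BMDM libraries. Each point is a library, and bars give the mean and SD of 3 libraries per genotype; Pparg overlaps between genotypes, the interferon-induced genes and Sptbn1 lie higher in T166A, and Plau lies lower (226 CPM in WT, 104.5 in T166A).

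Among 20 pathway lists fixed before the data were examined, the type I interferon response list was the only one that was higher in T166A BMDM by camera. All 31 measured members had positive log2 fold changes, with a median of 0.72. Of them 3 rose over all genes tested (Ifit1, Ifit2 and Ifit3), and 25 passed when adjusted over the list alone, among them, named after their values were seen, Isg15 (log2 fold change 0.70, SE 0.12) and Ifih1 (0.92, SE 0.16), an RNA sensor. The camera adjusted p was 4.06e-42 with the preset correlation of 0.01, and the adjusted p = 0.25 with an estimated correlation. The list's median was 0.95 in batch B1 and 0.43 in B2.

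Lists for energy metabolism were lower in T166A BMDM by the same test. Of 20 glycolysis genes, 0 passed over all genes tested by edgeR and 6 were lower when adjusted over the list alone. The list's median was -0.35 (camera adjusted p = 7.64e-07, adjusted p = 0.253 with an estimated correlation), with -0.26 in B1 and -0.46 in B2. Slc2a1, the main glucose importer of many cells, was not named by the fixed rule and had a log2 fold change of -0.74 (SE 0.14, edgeR adjusted p = 0.131). Of 33 oxidative phosphorylation genes, 0 passed over all genes and 1 was lower over the list alone, with a median of -0.25 (camera adjusted p = 1.1e-07, adjusted p = 0.687 with an estimated correlation) and batch values of -0.36 and -0.08. The fatty acid oxidation list had 0 of 19 members passing on either scale and a median of -0.25 (camera adjusted p = 0.00572, adjusted p = 0.56 with an estimated correlation). Fatty acid synthesis genes did not pass in BMDM, with 0 of 20 members called and a median of 0.07 (camera adjusted p = 0.493).

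Further lists were lower in T166A BMDM by camera. The pro-inflammatory list had a median of -0.48 (camera adjusted p = 0.0068, adjusted p = 0.687 with an estimated correlation). The growth factor and matrix remodelling list had one of -0.23 (camera adjusted p = 0.000269, adjusted p = 0.253 with an estimated correlation) and the NRF2 and oxidative stress list one of -0.32 (camera adjusted p = 1.33e-05, adjusted p = 0.253 with an estimated correlation). The endoplasmic reticulum stress list had one of -0.20 (camera adjusted p = 0.0267, adjusted p = 0.687 with an estimated correlation) and the cell cycle list one of -0.36 (camera adjusted p = 4.58e-05, adjusted p = 0.687 with an estimated correlation). Of the growth factor list, 1 of 29 members, Plau, fell over all genes, and 2 were higher and 5 lower over the list alone. The cell cycle list had 0 of 36 members passing over all genes and 6 lower over the list alone, with a median of -0.64 in B1 and 0.06 in B2. The pro-inflammatory list went from -0.61 in B1 to -0.11 in B2 and had 0 of 30 members passing over all genes. Of the 19 NRF2 and 22 endoplasmic reticulum stress members, 0 passed on either scale. At an unadjusted p of 0.05, 830 of all genes tested were lower and 856 higher, and DESeq2 and limma-voom called 138 and 28 lower, as given above for the full set. Altogether 9 of 20 lists passed with the preset correlation and 0 with an estimated correlation, and fry's directional test passed 0. Single libraries ended calls for the pro-inflammatory list (without WT replicate 1, median -0.13, camera adjusted p = 0.427) and the cell cycle list (without WT replicate 2, -0.23, camera adjusted p = 0.0741). The endoplasmic reticulum stress list lost its call in 4 cases (without WT replicate 1 or 2, or T166A replicate 1 or 2, camera adjusted p = 0.0837, 0.248, 0.247 and 0.126). With T166A replicate 3 left out, where genotype is estimated from the B1 libraries alone, 11 lists passed.

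The lists that did not pass in BMDM had small medians: glycerolipid and phospholipid synthesis 0.03 (camera adjusted p = 0.407), cholesterol synthesis 0.03 (0.357), PPAR target genes -0.05 (0.461), and LXR target genes 0.02 (0.685). The medians were also small for alternative activation 0.06 (0.439), MHC class II 0.01 (0.808), efferocytosis 0.10 (0.26), lysosome -0.05 (0.321), immediate early and heat shock genes -0.07 (0.547) and kinase and nuclear receptor partners of PPARg 0.19 (0.09). The alternative activation list had a positive median, a negative mean (-0.41) and a downward test direction.

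Markers of some other cells were lower in T166A BMDM by camera with its preset correlation, and a trend with transcript length differed between the libraries. Neutrophil genes (median -0.68), haematopoietic progenitor genes (-0.91) and osteoclast genes (-0.37) were lower by camera (adjusted p = 0.000494, 0.000494 and 0.00953), and 0 of these held with an estimated correlation, where the lowest adjusted p was 0.371. The other tested lists did not pass: macrophage 0.07, monocyte 0.20, dendritic cell -0.23, T and NK cell 0.32, fibroblast 0.55 and endothelial cell -0.20. T166A replicate 3 stood apart, with 244 CPM of the fibroblast collagen gene Col1a1 against 6.34 ± 7.25 CPM in WT libraries, and the fibroblast list had a median of -0.63 in B1 and 5.06 in B2. Transcripts of up to 1 kb had a median log2 fold change of -0.27 and those over 6 kb one of 0.34, and length correlated with the log2 fold change across genes (Spearman 0.44). The Spearman correlation of length with log2 CPM centred per gene was 0.16, -0.50 and -0.61 in WT replicates 1, 2 and 3. It was 0.59, 0.59 and -0.33 in T166A replicates 1, 2 and 3, so the trend varied within each genotype. With each library's length trend removed, an alternative chosen after seeing the data, 4 lists no longer passed. The medians were then -0.04 for oxidative phosphorylation (camera adjusted p = 0.0893), -0.14 for fatty acid oxidation (0.166), -0.09 for endoplasmic reticulum stress (0.166) and -0.40 for the pro-inflammatory list (0.0885), the last of which kept most of its -0.48. Sptbn1 no longer passed either (edgeR adjusted p = 0.129, range over its alternatives 1.99e-12 to 0.449), while the interferon list kept a median of 0.73.

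The second comparison asked what the T166A form changes in macrophages taken from a healing wound. By camera with its preset correlation, the skin macrophage fraction from T166A wounds held more transcripts of fatty acid synthesis and oxidation genes, less of the inflammatory and growth factor transcripts, and a different mix of markers of other cell types. With an estimated correlation the growth factor list passed (adjusted p = 0.023), and the synthesis (0.0514), oxidation (0.0514) and pro-inflammatory lists (0.166) did not. Of these lists, 11 of 22 synthesis, 6 of 19 oxidation and 15 of 32 pro-inflammatory members did not pass by edgeR. Tnf (chromosome 17, 35199367 to 35202007), a central inflammatory cytokine, fell from 746 ± 29.2 to 390 ± 32.2 CPM, and Il10 (chromosome 1, 131019845 to 131024970), an anti-inflammatory cytokine, fell from 1138 ± 62.6 to 736 ± 71.6 CPM. Fasn, which encodes fatty acid synthase, rose 2.38-fold from 62.8 ± 9.97 to 150 ± 46.9 CPM, and Scd1, a fatty acid desaturase gene, rose 2.46-fold. The adipocyte hormone gene Adipoq (chromosome 16, 23146536 to 23157968) rose 10.8-fold, from 0.916 ± 0.375 to 9.91 ± 2.29 CPM. Pparg transcripts were 28 ± 1.27 CPM in WT and 24.5 ± 3.34 CPM in T166A, which missed the threshold (log2 fold change -0.19, SE 0.08, edgeR adjusted p = 0.0776). It passed without T166A replicate 3 (-0.24, edgeR adjusted p = 0.0263) and with keratinocyte and fibroblast scores as covariates (-0.26, edgeR adjusted p = 0.0124), and over all alternatives the adjusted p ran from 0.0124 to 0.592 for Pparg in skin macrophages. Fasn and Scd1 were named after their values were seen.

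Of 15473 genes tested in skin, 1962 were higher and 2048 lower in T166A by edgeR, which is 25.9% of those tested. Changes of at least 2-fold were seen for 201 higher and 172 lower genes. The median absolute log2 fold change of called genes was 0.37. By the fixed rule, the largest rises with every T166A library above every WT library were those of Itih4 (14.7-fold, from 1.33 ± 0.415 to 19.7 ± 4.64 CPM), Adipoq, and Pck1 (9.98-fold), which encodes a key enzyme of gluconeogenesis and glyceroneogenesis. Next came Ucp1 (9.95-fold, from 2.27 ± 0.562 to 22.7 ± 11.3 CPM), the uncoupling protein of brown fat, Gpd1 (5.79-fold), the lipid droplet genes Cidec (5.76-fold) and Cidea (5.18-fold), and Cdo1 (5.03-fold). The largest falls were those of Corin (log2 fold change -3.59, SE 0.47, from 16.4 ± 2.85 to 1.35 ± 1.23 CPM, edgeR adjusted p = 0.000234), a serine protease gene, and Wif1 (-2.97, SE 0.38, from 15.8 ± 5.43 to 2.02 ± 1.1 CPM), which encodes a secreted Wnt inhibitor. They were followed by Pappa2 (-1.81), the C-type lectin genes Cd209g (-1.58) and Cd209f (-1.39), which are near-identical family members, Masp1 (-1.49), Tmprss2 (-1.47) and the complement gene C6 (-1.33). With the adipocyte score as a covariate, an alternative chosen after seeing the data, Itih4, Adipoq, Masp1 and Tmprss2 still passed (edgeR adjusted p = 0.00052, 0.012, 0.0397 and 0.000703) and the others did not. Ucp1 then had a log2 fold change of 0.69 (edgeR adjusted p = 0.491), Gpd1 0.47 (0.654), Cidec 0.87 (0.27), Cdo1 0.84 (0.217), Pck1 1.55 (0.0696) and Cidea 1.89 (0.0728). Corin had -1.68 (edgeR adjusted p = 0.367), Wif1 -2.31 (0.22), C6 -1.21 (0.192), Pappa2 -1.48 (0.0689), Cd209g -1.41 (0.0971) and Cd209f -1.71 (0.0592). This score correlated with genotype and widened the errors, for Corin from 0.47 to 0.93. Adipoq, Pck1, Cidec and Cidea are themselves part of the score, so their values with it are no independent test.

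**Figure D2:**
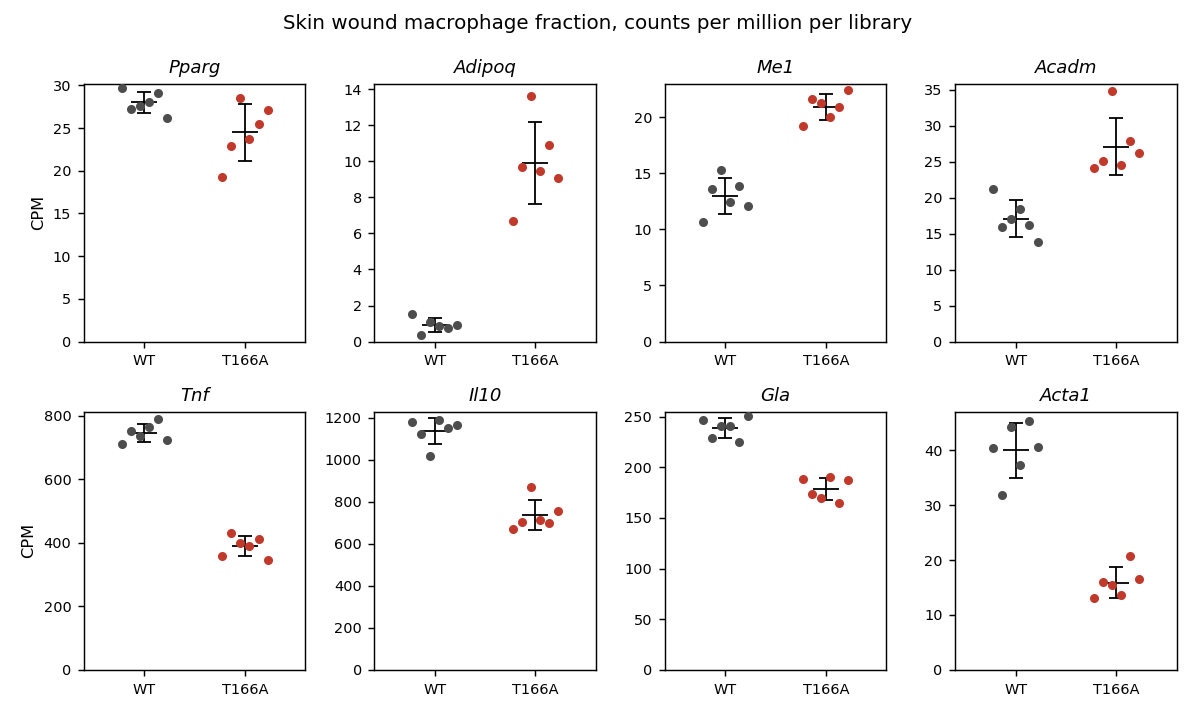
CPM of 8 named genes in the 12 skin libraries. Each point is a library, and bars give the mean and SD of 6 libraries per genotype; Adipoq, Me1 and Acadm lie higher in T166A, Tnf, Il10, Gla and Acta1 lie lower, and Pparg overlaps between genotypes (28 CPM in WT, 24.5 in T166A).

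Fatty acid synthesis genes were higher as a group in T166A skin macrophages, with 10 of 22 members higher, 1 lower and 11 not passing (11 and 1 when adjusted over the list alone). Besides Fasn and Scd1, Me1, which supplies NADPH, rose (log2 fold change 0.68, SE 0.08, edgeR adjusted p = 2.47e-06), and Mlxipl, a transcription factor gene of lipogenesis, rose from 0.264 to 1.73 CPM (2.70, SE 0.41, edgeR adjusted p = 4.16e-05). Acly, which the fixed rule did not name, had a log2 fold change of 0.02 (SE 0.05) and did not pass. The median was 0.25 (camera adjusted p = 1.96e-05, adjusted p = 0.0514 with an estimated correlation). Fatty acid oxidation genes had 13 of 19 members higher and 0 lower (15 and 0 over the list alone), with Acadm (0.66, SE 0.10, edgeR adjusted p = 4.39e-05) and Hadhb (0.48, SE 0.07, edgeR adjusted p = 2.48e-05) among them. The median was 0.22 (camera adjusted p = 4e-06, adjusted p = 0.0514 with an estimated correlation). Of 11 measured adipocyte markers, 10 rose, with a median of 1.74. Over the 6 T166A libraries, the mean log2 CPM of the fatty acid synthesis list followed that of the adipocyte list (Pearson r = 0.99, exact permutation p = 0.00139, adjusted 0.00556 over 4 relations; Spearman rho = 1, exact permutation p = 0.00278, adjusted 0.0111), and without the 2 libraries farthest from the median r was 0.89. These permutation tests counted both tails. The mean of the oxidation list gave r = 0.88 (exact permutation p = 0.0264, adjusted 0.0528; rho = 0.94, exact permutation p = 0.0167, adjusted 0.0334) and 0.84 without those libraries. Over the 6 WT libraries r was 0.49 for synthesis (exact permutation p = 0.311, adjusted 0.311; rho = 0.31, p = 0.564) and 0.52 for oxidation (exact permutation p = 0.294, adjusted 0.311; rho = 0.37, p = 0.497), with -0.28 and 0.19 without the 2 farthest libraries. With the adipocyte score as a covariate, Mlxipl turned to -0.93 (edgeR adjusted p = 0.634), and Me1 (0.50, edgeR adjusted p = 0.23), Acadm (0.20, 0.737) and Hadhb (0.29, 0.453) missed the threshold. Both lists then missed it as well (medians 0.05 and 0.09, camera adjusted p = 0.56 and 0.398; over all alternatives 1.52e-08 to 0.56 and 1.26e-06 to 0.398).

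**Figure D3:**
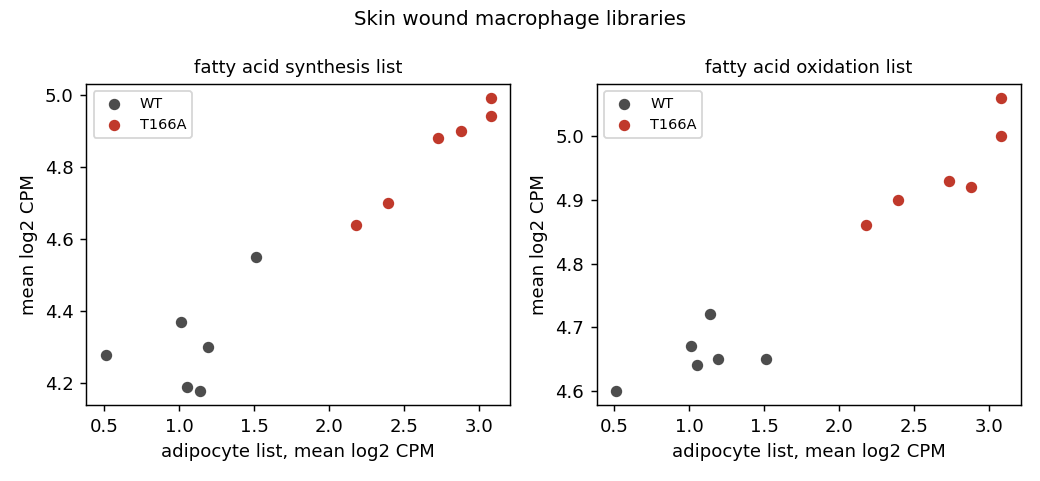
Mean log2 CPM of the fatty acid synthesis list (left) and the fatty acid oxidation list (right) against the mean log2 CPM of the adipocyte list, without genes shared between lists. Each point is 1 of 12 skin libraries; WT libraries lie at or below 1.51 on the adipocyte axis and T166A libraries at or above 2.18.

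Other lipid lists moved less. PPAR target genes went both ways, with 9 of 25 members higher and 4 lower (9 and 5 over the list alone), and did not pass as a group (median -0.03, mean 0.31, camera adjusted p = 0.0845 with an upward direction). Acsl1 (0.52, SE 0.06, edgeR adjusted p = 7.68e-07), an acyl-CoA synthetase gene, and Cidec rose, while the lipid carrier gene Fabp5 (-0.37, SE 0.05) and the lipid droplet gene Plin2 (-0.29, SE 0.06) fell. Cd36, a fatty acid scavenger receptor, had a log2 fold change of 0.08 (SE 0.11). Fabp5, Plin2 and Cd36 were not named by the fixed rule. The glycerolipid list had 6 of 29 members higher and 8 lower (9 and 8 over the list alone), with Pcyt1a, an enzyme gene of phosphatidylcholine synthesis, lower (-0.50, SE 0.06, edgeR adjusted p = 6.51e-07), and a median of 0.02 (camera adjusted p = 0.962). The cholesterol synthesis list had 2 of 23 higher and 4 lower (2 and 4 over the list alone), with Insig1 (edgeR adjusted p = 4.36e-06) and Fdft1 (edgeR adjusted p = 0.000351) among those that fell, and a median of -0.06 (camera adjusted p = 0.282). LXR target genes were lower as a group, with 2 of 18 higher and 9 lower (3 and 10 over the list alone) and a median of -0.21 (camera adjusted p = 0.00312, adjusted p = 0.166 with an estimated correlation). Nr1h3, which encodes the receptor LXR alpha, fell (-0.56, SE 0.08, edgeR adjusted p = 1.44e-05), as did Arl4c (-0.36, SE 0.05). Oxidative phosphorylation genes had 10 of 33 members higher and 0 lower on both scales and a median of 0.12 (camera adjusted p = 0.00388, adjusted p = 0.403 with an estimated correlation), with Sdhb (0.24, SE 0.06) and Uqcrc2 (0.22, SE 0.06) higher. The glycolysis list had 8 of 20 members higher and 1 lower on both scales and did not pass (median 0.07, camera adjusted p = 0.0845), with Pfkl higher and Hk2 lower. With the adipocyte covariate the PPAR target list passed in the downward direction (median -0.25, camera adjusted p = 0.0336), but its members Cidec and Fabp4 are part of that score. Among its other alternatives the list also passed upward, with a lowest camera adjusted p of 0.0114. Pcyt1a (-0.47, edgeR adjusted p = 0.0742), Fdft1 (-0.35, 0.161), Nr1h3 (-0.31, 0.467), Sdhb (0.47, 0.0753), Uqcrc2 (0.38, 0.155) and Pfkl (0.07, 0.874) then missed the threshold. The log2 fold changes of Nr1h3 and Pfkl had shrunk. Those of Pcyt1a, Fdft1, Sdhb and Uqcrc2 were about as large as before or larger, so their calls ended through wider errors (0.15 against 0.06 for Pcyt1a). With the neutrophil score as a covariate Sdhb (0.16, edgeR adjusted p = 0.204) and Uqcrc2 (0.18, 0.119) missed it.

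Inflammatory, growth factor and early response genes were lower as groups in the T166A skin macrophage fraction. Of 32 pro-inflammatory genes, 4 were higher and 13 lower (4 and 14 over the list alone), led by Tnf (log2 fold change -0.94, SE 0.06, edgeR adjusted p = 1.23e-10) and the inflammasome sensor gene Nlrp3, which fell from 602 ± 17.6 to 345 ± 19.1 CPM (edgeR adjusted p = 1.23e-10). The median was -0.12 (camera adjusted p = 3.12e-05, adjusted p = 0.166 with an estimated correlation). Of 32 growth factor and matrix remodelling genes, 1 was higher and 16 lower (3 and 17 over the list alone), including the metalloprotease gene Mmp19 (from 1876 ± 30.7 to 1288 ± 55.2 CPM, edgeR adjusted p = 2.35e-08) and Il10 (edgeR adjusted p = 8.76e-08). This call held with an estimated correlation (median -0.21, camera adjusted p = 2.79e-07, adjusted p = 0.023 with an estimated correlation). Of 22 alternative activation genes, 0 were higher and 10 lower (1 and 10 over the list alone), including the transcription factor genes Klf4 (-0.66, SE 0.06, edgeR adjusted p = 3.97e-08) and Egr2 (-0.58, SE 0.07, edgeR adjusted p = 3e-06). The median was -0.26 (camera adjusted p = 4e-06, adjusted p = 0.0837 with an estimated correlation). Arg1, another member, which the fixed rule did not name, had a log2 fold change of 0.33 (SE 0.15, edgeR adjusted p = 0.135). Of 25 immediate early and heat shock genes, which respond to cell handling as well as to signalling, 0 were higher and 20 lower (0 and 23 over the list alone), including Atf3 (from 592 ± 57.7 to 405 ± 17.7 CPM) and the chaperone gene Dnajb1 (from 163 ± 7.35 to 119 ± 7.41 CPM). The median was -0.45 (camera adjusted p = 9.58e-18, adjusted p = 0.023 with an estimated correlation). Dnajb1 missed the threshold with the adipocyte covariate (-0.19, edgeR adjusted p = 0.463). All 14 macrophage markers also had negative log2 fold changes. Their median of -0.32 was a larger fall than those of the pro-inflammatory, growth factor and alternative activation lists. Whether a lower share of macrophage RNA, with a changed mix of other cells, gave the falls of these lists was not tested.

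Lysosomal, phagocytic and antigen presentation genes were also lower. Of 30 lysosome genes, 0 were higher and 22 lower (1 and 24 over the list alone), including the hydrolase genes Gla (-0.42, SE 0.05, edgeR adjusted p = 1.73e-06) and Neu1 (-0.39, SE 0.05, edgeR adjusted p = 1.24e-05). The median was -0.22 (camera adjusted p = 1.81e-07, adjusted p = 0.166 with an estimated correlation). Of 30 efferocytosis genes, 2 were higher, among them Itgb3 (0.57, SE 0.08), and 15 lower, among them the bridging protein gene Gas6 (-0.43, SE 0.06) (3 and 19 over the list alone). The median was -0.24 (camera adjusted p = 0.00119, adjusted p = 0.131 with an estimated correlation). Of 11 MHC class II genes, 0 were higher and 8 lower on both scales, including H2-DMb1 and H2-DMa (each -0.33, SE 0.07 and 0.08). The median was -0.21 (camera adjusted p = 0.00293, adjusted p = 0.319 with an estimated correlation). The macrophage marker list fell in parallel with these groups, with 0 of 14 members higher and 11 lower (0 and 13 over the list alone) and a median of -0.32 (camera adjusted p = 2.85e-09, adjusted p = 0.168 with an estimated correlation). Lyz2 went from 5420 ± 480 to 4279 ± 163 CPM. Adgre1, which encodes F4/80 and was not named by the fixed rule, went from 884 ± 86.7 to 687 ± 33.4 CPM. Under the adipocyte covariate Gla (-0.30, edgeR adjusted p = 0.224), Neu1 (-0.48, 0.0631), Itgb3 (0.69, 0.0682), H2-DMa (-0.43, 0.279) and Lyz2 (-0.44, 0.134) missed the threshold, all but Gla with log2 fold changes as large as before or larger and with wider errors.

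Cell cycle genes were higher, with 14 of 36 members higher and 2 lower (20 and 2 over the list alone), including the replication genes Mcm6 (0.45, SE 0.07, edgeR adjusted p = 2.52e-05) and Top2a (0.44, SE 0.07, edgeR adjusted p = 3.61e-05). The median was 0.30 (camera adjusted p = 0.000127, adjusted p = 0.0837 with an estimated correlation). The type I interferon list, which was higher in BMDM, did not pass in skin. Of its 31 members, 2 rose, Xaf1 (0.26, SE 0.07, edgeR adjusted p = 0.00942) and Ddx58 (0.20, SE 0.07, edgeR adjusted p = 0.0378), or 1 when adjusted over the list alone, and the median was 0.09 (camera adjusted p = 0.282). With the neutrophil covariate both missed the threshold (log2 fold change 0.11 each, edgeR adjusted p = 0.45 for Xaf1 and 0.457 for Ddx58). With the adipocyte covariate both turned, to -0.05 and -0.24, and the list passed in the downward direction (median -0.24, camera adjusted p = 0.00191), while with keratinocyte and fibroblast covariates it passed upward (0.13, 0.018). Over its alternatives the adjusted p of Ddx58 in skin ran from 0.0168 to 0.457. It also missed the threshold with transcripts summed (edgeR adjusted p = 0.0615) and without WT replicate 2, 4 or 5 or T166A replicate 2, 3, 4 or 6, with log2 fold changes of 0.14, 0.19, 0.18, 0.18, 0.19, 0.21 and 0.19. The NRF2 list had 4 of 19 higher, with Nqo1 (1.27, SE 0.24, edgeR adjusted p = 0.000777), and 2 lower, with the ferritin gene Ftl1 (-0.24, SE 0.07), and 5 and 2 over the list alone (median 0.08, camera adjusted p = 0.317). It passed with the adipocyte covariate (0.47, camera adjusted p = 1.2e-05) and with keratinocyte and fibroblast covariates (0.11, 2.72e-05). The endoplasmic reticulum stress list had 5 of 23 higher, with Chac1 (1.99-fold), and 4 lower, with 5 and 6 over the list alone (median -0.06, camera adjusted p = 0.849). The list of kinase and nuclear receptor partners of PPARg had 3 of 21 higher and 5 lower on both scales, with Cebpa (-0.46, SE 0.06) and the coactivator gene Ncoa1 (-0.45, SE 0.07) lower (median -0.02, camera adjusted p = 0.395). Under the adipocyte covariate Mcm6 (0.58, edgeR adjusted p = 0.0682), Top2a (0.59, 0.0645), Nqo1 (1.83, 0.0983), Chac1 (0.89, 0.0732), Cebpa (-0.37, 0.258), Ncoa1 (-0.60, 0.0739) and Ftl1 (-0.02, 0.964) missed the threshold. Only Ftl1 was near 0 by then. Mcm6, Top2a, Nqo1 and Ncoa1 had larger log2 fold changes than before, so their calls ended through wider errors (0.19 against 0.07 for Mcm6). With the neutrophil covariate Nqo1 missed the threshold (0.85, edgeR adjusted p = 0.0734). In all, 12 of 20 lists passed with the preset correlation and 2 with an estimated correlation, the growth factor list and the immediate early list, while fry's directional test passed 14. Among these were glycolysis (upward, fry adjusted p = 0.0475) and cholesterol synthesis (downward, 0.0262), which camera did not pass.

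**Figure D4:**
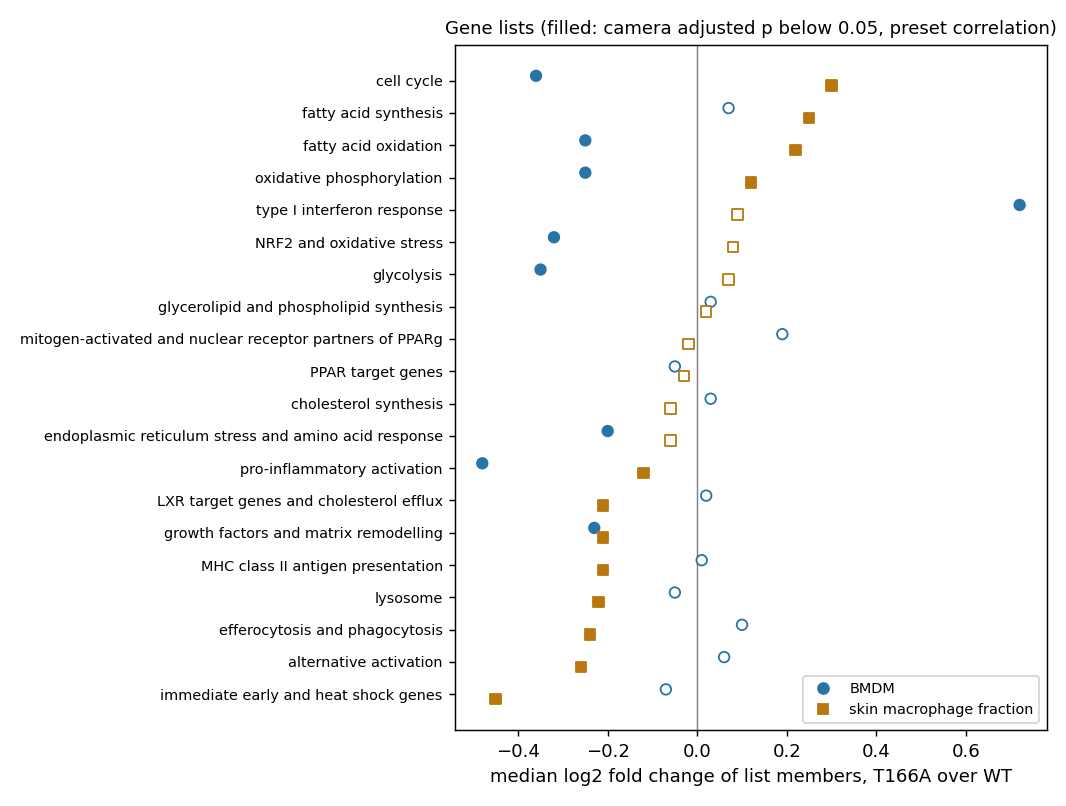
Median log2 fold change (T166A over WT) of the members of each of 20 pathway lists in BMDM (circles) and in the skin macrophage fraction (squares). Filled symbols passed camera with the preset correlation, 9 lists in BMDM and 12 in skin; the interferon list has a median of 0.72 in BMDM and 0.09 in skin.

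Markers of other cell types differed between the genotypes of the bead fraction in both directions. Adipocyte markers (median 1.74, camera adjusted p = 6.15e-18), pericyte and smooth muscle markers (0.83, 5.53e-08; Rgs5 from 246 ± 20.4 to 388 ± 70.9 CPM) and endothelial markers (0.44, 7.74e-05; Pecam1 from 380 ± 47 to 549 ± 75 CPM) were higher. Skeletal muscle markers were lower, with 9 of 10 members lower and Acta1 falling from 39.9 ± 4.95 to 15.9 ± 2.78 CPM (median -1.26, camera adjusted p = 2.62e-11). With an estimated correlation the adjusted p = 0.0523 for adipocyte, 0.122 for pericyte, 0.318 for endothelial and 0.0555 for skeletal muscle markers. Fibroblast (median -0.16), keratinocyte (0.05), hair follicle (-0.16), monocyte (-0.04), neutrophil (-0.61), dendritic cell (-0.11), mast cell (-0.60), Schwann cell (0.70), erythroid (-0.55), osteoclast (0.22) and haematopoietic progenitor (0.42) lists did not pass by camera, and T and NK cell, B cell, eosinophil and melanocyte lists had fewer than 5 measured members. By fry's directional test the neutrophil (adjusted p = 0.009), Schwann cell (0.009) and haematopoietic progenitor (0.00349) lists did pass. The fibroblast gene Col3a1 was at 3981 ± 613 CPM in WT and 3755 ± 752 CPM in T166A libraries, so transcripts of cells other than macrophages were abundant in both. Fabp4, which adipocytes and macrophages both express, was at 514 ± 73.4 and 517 ± 75.1 CPM. Under the adipocyte covariate Pecam1 (0.09, edgeR adjusted p = 0.884) and Rgs5 (0.21, 0.759) missed the threshold, and Col3a1 and Fabp4 passed with the opposite sign (0.90 and -0.67). Fabp4 is itself part of that score. In the BMDM tables, 2 of the 12 adipocyte markers were measured.

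The third comparison asked whether the effect of T166A differed between BMDM and skin macrophages. Rhoj, which encodes a small GTPase of the cytoskeleton, had a log2 fold change of -0.97 (SE 0.22) in BMDM and 0.66 (SE 0.09) in skin, and Eps8, an actin regulator gene, one of 0.68 (SE 0.14) in BMDM and -0.51 (SE 0.06) in skin. Differences are signed, the log2 effect in skin minus that in BMDM. The median difference was -0.61 for interferon genes, 0.58 for cell cycle, 0.49 for fatty acid oxidation and 0.45 for glycolysis genes. The medians of the last 3 lists were -0.36, -0.25 and -0.35 in BMDM and 0.30, 0.22 and 0.07 in skin. The edgeR interaction test with a dispersion shared by both sources called 2367 of 16586 genes, 1012 with a positive and 1355 with a negative difference. With RLE size factors the split was 763 positive and 1627 negative. On simulated counts with each source's own spread, this test made 275 false calls among 365 (75.3%), so its count is not read as a number of differing genes. The difference of the separate edgeR fits with a p on Satterthwaite degrees of freedom, an alternative chosen on the simulated counts, made 10 false calls among 72 (13.9%) and called 310 of 12692 genes, 111 positive and 199 negative. All 310 were also called by the shared fit. The length trend differed between the sources (Spearman 0.44 in BMDM, 0.06 in skin). With it removed in both, an alternative chosen after seeing the data, the separate edgeR fits called 136 positive and 273 negative differences, among them 237 of the 310. The median differences were then -0.79 for interferon, 0.63 for cell cycle, 0.35 for fatty acid oxidation and 0.36 for glycolysis genes, and 0.19 for oxidative phosphorylation genes against 0.37 without the correction.

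By the separate edgeR fits, 11 of 31 interferon genes had a negative and 0 a positive difference. The numbers were 8 positive and 0 negative of 36 cell cycle genes, 6 and 0 of 20 glycolysis genes, and 5 and 0 of 19 fatty acid oxidation genes. They were 2 and 0 of 33 oxidative phosphorylation genes, 1 and 0 of 20 fatty acid synthesis genes, 3 and 0 of 20 PPAR target genes and 0 and 3 of 25 immediate early genes. With the length trend removed, they were 0 positive and 14 negative for interferon, 8 and 0 for cell cycle, 5 and 0 for glycolysis, 5 and 0 for fatty acid oxidation, 1 and 0 for fatty acid synthesis, 3 and 1 for PPAR target and 0 and 6 for immediate early genes. Of the oxidative phosphorylation genes, edgeR then called 0 in either direction, with 7 at an unadjusted p under 0.05. The 10 genes named by the rule passed both tests. Their differences in the shared fit were 1.66 for Rhoj, 1.25 for Procr, 1.10 for Pcdh7, 0.99 for Plau and 0.90 for the glycolytic gene Pgk1. They were -1.16 for Eps8, -1.03 for Med13, -0.84 for Baz1a, -0.96 for Nfat5 and -1.99 for Clcn5. The adjusted p from the separate edgeR fits ranged from 0.00607 to 0.0311. With the length trend removed, Med13 (-0.66, edgeR adjusted p = 0.0599) and Nfat5 (-0.51, 0.137) missed the threshold, and over all alternatives the adjusted p ran from 1.92e-17 to 0.0599 for Med13 and from 1.61e-15 to 0.137 for Nfat5. BMDM libraries expressed the Y-linked gene Eif2s3y at 25.6 ± 4.43 CPM in WT, and skin libraries expressed Xist at 1281 ± 142 CPM in WT, so the sources differed in sex as well as in cell type.

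Across 12693 genes tested in both sources, the log2 fold changes had a Spearman correlation of 0.007 across genes. Leaving out single libraries gave -0.071 to 0.051. Between batches B1 and B2 of BMDM alone the correlation was 0.05, so a value near 0 does not show that the sources responded unalike. No gene was higher in both sources by edgeR (0 shared, 0.95 expected for independent lists; 856 BMDM genes were higher at an unadjusted p of 0.05). Plau was the single gene lower in both (1 shared, 0.14 expected, Fisher's exact p = 0.141), with a log2 fold change of -1.12 in BMDM and -0.17 (SE 0.05) in skin. Over the genes ranked in the top 500 by p in BMDM, in skin or in both, the correlation was 0.135. They were selected on the same effects that were then correlated.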

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

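The tests with the adipocyte covariate, the comparison of lists with all genes of the same libraries, the skeletal muscle list, the immediate early genes, the separate length tests of oxidative phosphorylation and glycolysis, and the difference with Satterthwaite degrees of freedom, with or without the length trend, were chosen after the results they address had been seen.

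In 6 of 150 groups of 6 skin libraries, a library lay far from the others, where chance gives about 7.5. The gap to the nearest library, as a share of the group's range, was 0.674 for Cidec in WT replicate 1 (highest, 3.78 CPM). It was 0.665 for Cd209g in WT replicate 2 (lowest, 16.2 CPM), 0.659 for Itgb3 in WT replicate 2 (highest, 225 CPM) and 0.653 for Fdft1 in T166A replicate 2 (lowest, 91.2 CPM). It was 0.65 for Acadm (highest, 34.8 CPM) and 0.855 for Fn1 (lowest, 1101 CPM), both in T166A replicate 3.

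The effect of T166A differed between BMDM and skin for 26 of 103 named genes by the separate edgeR fits (adjusted p 0.00294 to 0.0444). Of these, 10 were named for this difference and others for a large change in a single source, so the count is no measure of how common such differences are. Over all genes it was 310 of 12692. The log2 effect in skin minus that in BMDM was positive for Gpd1 (3.03), Nqo1 (1.97), Rhoj (1.62), Procr (1.21), Pcdh7 (1.06), Acadm (0.99), Plau (0.95), Pgk1 (0.86), Pfkl (0.77) and Hadhb (0.75). It was negative for Cd209f (-2.21), Clcn5 (-2), Ifi203 (-1.35), H2-Q7 and H2-Q9 (-1.27 each), Ms4a4c (-1.25), Eps8 (-1.19), Med13 (-1.07), Ifit2 (-1.03), Nfat5 (-1), Ifit1 (-0.94), Sptbn1 (-0.93), Baz1a (-0.88), Pcyt1a (-0.81), Ifit3 (-0.79) and Ccr2 (-0.73). Of 40 splits of the libraries within each source, only the real one gave as many genes: 310 against at most 72 for the separate fits and 2367 against at most 1172 for the shared fit (1 of 40 each). The splits redrew the genotype in both sources and did not keep the BMDM batches balanced. They therefore ask whether T166A had any effect in either source, and cannot exclude chance for a difference between the sources. The shared fit called a median of 381 genes in the other splits. Sex, cell preparation and the transcript length trend (Spearman 0.44 in BMDM, 0.06 in skin) also differ between the sources, so the differences cannot be assigned to cell type. With the length trend removed 409 genes differed, among them 237 of the 310, and the splits were not repeated for that fit.

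Fatty acid synthesis and oxidation genes were higher in T166A skin macrophages by camera with its preset correlation, though not with an estimated correlation (adjusted p = 0.0514 each), and adipocyte RNA in the bead fraction is a candidate explanation. With the adipocyte score as a covariate the synthesis list's median went from 0.25 to 0.05 and the oxidation list's from 0.22 to 0.09. Within the T166A libraries the adipocyte score correlated with the synthesis score (r = 0.99, exact permutation adjusted p = 0.00556) and the oxidation score (r = 0.88, adjusted p = 0.0528). Within the WT libraries r was 0.49 and 0.52 (exact permutation adjusted p = 0.311 each). The calls ended partly because the median SE of members grew from 0.09 to 0.24 and from 0.07 to 0.20, since the score and the genotype were nearly the same variable (r = 0.93 over all 12 libraries, which fall into separate clusters). RLE size factors moved the median of all genes only from 0.01 to 0 and could not test normalization. The synthesis members' median relative to all genes of the same library differed by 0.30 between the genotypes (SD 0.10 in WT and 0.09 in T166A libraries, exact p = 0.00216, the smallest that 924 groupings can give). No scaling factor changes this difference, so a scaling factor alone does not explain it. The list had already been called in these libraries by camera, which also compares it with the other genes, so this p is no independent evidence. For both lists adipocyte RNA and an effect of T166A in macrophages cannot be told apart, and the latter stays open, untested.

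Macrophage, lysosome and inflammatory genes were lower in T166A skin macrophages by camera with its preset correlation, though not with an estimated correlation (adjusted p = 0.168, 0.166 and 0.166). A lower share of macrophages alone would raise the markers of the other cells alike, but skeletal muscle markers had a median of -1.26 while adipocyte markers had one of 1.74. A lower share together with a changed mix of the other cells is not excluded by these values and was not tested. The same limit holds for the growth factor (median -0.21) and alternative activation (-0.26) lists. All 14 macrophage markers had negative log2 fold changes, with a median of -0.32, against -0.22 for the lysosome and -0.12 for the pro-inflammatory list. Relative to all genes of the same library, the members' median differed by -0.23 between the genotypes (SD 0.08 in WT and 0.07 in T166A libraries, exact p = 0.00216). The difference was -0.31 for macrophage, -0.22 for lysosome and -0.21 for pro-inflammatory genes. No scaling factor changes these differences, so a scaling factor alone does not explain them. The lists had already been called by camera in these libraries, so this p is no independent evidence. A difference in the time or handling of the cell preparation may contribute: immediate early and heat shock genes had a median of -0.45, and since the labels give no preparation day, handling and genotype cannot be told apart. An effect of T166A on macrophage activation stays open, untested.

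Interferon genes were higher in T166A BMDM, and metabolic lists lower, by camera with its preset correlation, and with an estimated correlation 0 lists passed. With the length trend removed and the replicate block, the interferon median was 0.73, which argues against transcript length as its cause. Without T166A replicate 3, the library rich in stromal transcripts, it was 0.95, which is the batch B1 estimate again. The length correction, with pairing by the block, left -0.04 for oxidative phosphorylation, so that fall may follow from the length trend, and -0.24 for glycolysis. The first written test covered both lists together and was split once they came apart. An effect of T166A or of culture conditions on interferon signalling stays open, untested.

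For BMDM, the 10 possible splits are too few for a share under 0.05. The real split gave 9 genes and the highest other 14, with WT replicates 1 and 3 and T166A replicate 3 on the same side, and 2 splits reached 9. The split with 14 genes puts both B2 libraries on the same side, so it is not balanced within batch as the real one is. Over the 6 splits balanced within batch, and over the 4 that part every same-numbered pair, the highest other was 0 genes by edgeR. For lists the real value was 9 and the highest other 12, with 4 splits reaching 9, and 12 was also the highest other over the balanced splits and over those parting the pairs. Every other BMDM split put unequal numbers of WT and T166A libraries on a side, so part of a genotype difference remained in it. In skin, 1 of 100 splits, out of 462 possible, reached 4010 genes, the real one (highest other 1346), so a chance division of these libraries is unlikely to give this count. The labels do not clearly give separate animals and give no preparation day. The splits therefore cannot exclude a cause shared by the libraries of a genotype. For skin lists, 14 of 100 splits reached 12 (highest other 14). The other splits that reached 12 kept most WT libraries on the same side, so part of a genotype difference remained in them. Splits with as many WT as T166A libraries on each side reached at most 8 lists. The share of 14 in 100 therefore does not show how many lists chance would call with the preset correlation, and chance is not excluded.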

How the results depend on the processing

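The length, adipocyte covariate, transcript sum and Satterthwaite alternatives were chosen after seeing the data. BMDM counts rested on few residual degrees of freedom. Against 8 higher and 1 lower BMDM genes, the counts were 85 and 22 without a filter, 231 and 138 with DESeq2, 147 and 28 with limma-voom, 20 and 0 in batch B1 alone by edgeR, 16 and 2 with the length trend removed, and 25 and 5 with the replicate block and the length trend removed. They were 0 and 0 without a batch term and 0 and 0 with transcripts summed by edgeR (929 and 1557 genes at an unadjusted p under 0.05), and 2 genes were lower with RLE size factors, with the stricter filter and with the replicate block. Leaving out single libraries gave 0 to 18 higher and 0 to 8 lower. BMDM lists numbered 0 with an estimated correlation, 0 by fry, 5 with the length trend removed and 5 with the replicate block as well, against 9. Skin lists numbered 2 with an estimated correlation, against 12. Skin genes numbered 277 higher and 550 lower with the adipocyte covariate, which nearly matches genotype and widened the errors. With the neutrophil covariate 1517 genes were higher and 1601 lower, 2594 of the 4010 calls were kept, and 6 named genes weakened, against 40 with the adipocyte covariate. Pparg in skin was -0.26 with keratinocyte and fibroblast covariates and -0.24 to -0.13 without single libraries. The direction turned for Col3a1 (0.15) and Fabp4 (-0.16) with keratinocyte and fibroblast covariates, and with the adipocyte covariate for Mlxipl (-0.93), Xaf1 (-0.05), Ddx58 (-0.24), Col3a1 (0.90), Fabp4 (-0.67), the PPAR target list (-0.25) and the interferon list (-0.24). Col3a1 is itself part of the fibroblast score, and Fabp4 and Cidec, members of the PPAR target list, are part of the adipocyte score. Interaction genes numbered 1249 by separate fits with a normal p and 310 with Satterthwaite degrees of freedom, which counts fewer degrees of freedom, or 409 with the length trend removed as well, where Med13 (-0.66) and Nfat5 (-0.51) missed the threshold. The correlation of effects was 0.135 over the genes in the top 500 of BMDM, of skin or of both. For the other shifts the cause was not tested. Of the comparisons of lists and of named genes other than Pparg with their alternatives, 427 BMDM gene values stayed on their side of the threshold and 65 weakened; for BMDM lists 242 stayed, 5 strengthened and 33 weakened; for skin genes 1551 stayed, 14 strengthened, 55 weakened and 7 turned; for skin lists 354 stayed, 12 strengthened, 12 weakened and 2 turned. For interaction genes 248 values stayed and 2 weakened. Batch B2 alone holds a single library per genotype and was given as values only.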

Other observations

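The test of genes near Pparg was chosen after the skin results had been seen.

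Mast cell and stem cell receptor gene Kit was higher in the T166A skin fraction (from 52.9 ± 4.46 to 86.7 ± 13.4 CPM, n = 6 each), and so was Cd34 (from 102 ± 6.8 to 128 ± 10.9 CPM). The mast cell list did not pass, and Kit went against it. Of its 6 measured members, Kit alone had a positive log2 fold change, 5 had negative ones and 3 were called lower (median -0.60). The neutrophil gene Csf3r fell from 202 ± 17.6 to 158 ± 26.9 CPM (log2 fold change -0.35, SE 0.10). With the adipocyte covariate Kit (0.31, edgeR adjusted p = 0.507), Cd34 (0.23, 0.499) and Csf3r (-0.65, 0.214) missed the threshold, as did Csf3r with the neutrophil covariate (-0.37, 0.103). Kit and Cd34 had smaller log2 fold changes than without it (0.71 and 0.33), whereas that of Csf3r was as large or larger and its calls ended through wider errors (0.28 with the adipocyte and 0.15 with the neutrophil covariate). Csf3r is itself part of the neutrophil score. The hair keratin gene Krt71 varied widely between libraries of the same genotype, with 56.3 ± 48.4 CPM in WT and 60.4 ± 58.5 CPM in T166A.

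Variants of another strain carried along with the edited Pparg locus could change the expression of nearby genes. Of 257 genes within 20 Mb of Pparg on chromosome 6, 80 were called in skin (31.1%), against 25.8% of 15216 other genes (Fisher's exact p = 0.0617), which leaves this open. In BMDM edgeR called 0 of 224 nearby genes, where 9 of 13137 genes were called in all (1686 at an unadjusted p under 0.05, 231 higher and 138 lower by DESeq2).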
